A study of Pimephales promelas with 15 samples.

How the data were processed

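Total RNA from the hypothalamus of female fathead minnows (Pimephales promelas) was hybridised to 15 two-colour Agilent oligonucleotide arrays. Per the labels' protocols, the Cy5 channel of each array held the pool of 4 hypothalami from 1 tank, and the Cy3 channel held a common reference pooled from 96 samples of male and female hypothalamus and telencephalon. RNA integrity numbers were above 8.2 per the labels' protocols. Dyes were not swapped, so each ratio is Cy5 over Cy3 and a dye effect shared by all arrays cancels between groups. Each array carried 15744 spots, of which 536 were control spots and 15208 were probes of 60 bases, each spotted once.

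The scanner files hold intensity values per spot, made by the authors with Agilent Feature Extraction 9.5.3.1, per the file headers. The same files hold a log10 ratio of the processed red and green signals, per the file headers, which was used only through those processed signals. The deposited per-array tables hold raw and normalized intensity values of both channels, and the method behind the normalized columns is not given in the sources used here. Their deposited log2 ratio is also the value of the series-wide table. When tested, both equalled the log2 of the deposited raw Cy5 over raw Cy3 values to within 1.85e-08. The raw Cy5 values equalled the scanner's median signals on the first array, the only array checked, and raw Cy3 was not checked. The deposited ratio is therefore neither dye-normalized nor centred, and its Cy5 values on that array were not background-subtracted. The column medians of the series-wide table ran from -0.31 to 1.53. The median log2 ratio of the authors' normalized channels, in contrast, lay between 0.0042 and 0.038 on every array.

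The main values were computed from the mean spot signals and the median local backgrounds with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots and spots marked as outliers at weight 0. Control spots were then removed and outlier spots set to missing. No step between arrays was applied. A probe was kept where its Cy5 signal was well above background on at least 3 of the 15 arrays, which left 14625 probes. No array held the same values as another, and each was counted as 1 replicate.

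Groups were taken from the labels. Control fish (4 arrays) and fish exposed to the mill effluents coded KM4 (3 arrays), TM5 (4 arrays) and TM6 (4 arrays) were fitted together with lmFit and eBayes, so that the 4 groups shared 1 estimate of the spread per probe. Each array is a separate tank. Adjusted p-values are Benjamini-Hochberg values over the 14625 probes within a comparison, and a probe is called at an adjusted p under 0.05. The replicate codes give slide, array row and array column and are not shared between groups, so they pair no arrays. The number of probes well above background was compared between groups with a two-sided exact permutation test. The precision of each value is limited by the 3 or 4 arrays per group.

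The design, the tests, the rule for named items and the first set of alternatives were fixed before the data were examined. The rule takes, for each effluent against control, the largest rises and falls among called probes, filled with the smallest unadjusted p where too few were called. The files do not pair probes with genes. The description of 0 of the 15208 probes names a gene, and 0 probe IDs occur in the reference gene table for this species (assembly fPimPro1.hap1.1, 64593 genes). The rule was therefore applied to probe IDs, and each is given with its sequence. The number named in each direction was 2, fewer than the number fixed beforehand. For the same reason the 34 gene lists fixed beforehand could not be matched, no gene list was tested, and genome positions are not given.

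The alternatives comprised other background corrections, the scanner software's processed signals, median centring, scaling or Aquantile between arrays, other filters, slide as a block or each slide alone, other variance models, array weights, the series-wide table, an unmoderated test, other thresholds and leaving out each array in turn. Alternatives chosen after seeing the data were the authors' normalized channels, subtraction of a GC trend (lowess, span 0.4) or of a smooth surface over the array (loess, span 0.1), array row as a fixed or random block, and leaving out 2 arrays together. The fit was tested on simulated data with 200 changed probes among 14252. For KM4 against control it called 26.9% of the probes changed by 0.5 on the log2 scale and 89.6% of those changed by 1, with 12 false calls among 155. For TM5 against control it called 41.8% and 91.0%, with 7 false calls among 160, and for TM6 against control 43.3% and 91.0%, with 11 among 166. These simulated errors were independent between probes.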

Results

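Sexually mature fathead minnows, a small freshwater fish used in effluent testing, were held for 5 days in undiluted (100%) effluent from pulp and paper mills coded KM4, TM5 and TM6, or under control conditions. Tanks held 4 females and 2 males, and 4 tanks were used per effluent. Transcript abundance in the female hypothalamus was measured on 15 arrays, with 4 control, 3 KM4, 4 TM5 and 4 TM6 tanks. Arrays are named by their label, in which CNHF marks control. Slide 1 carried 7 arrays and slide 2 carried 8, and both held all 4 groups. Each slide had 2 rows of arrays, and KM4 and control shared 0 of the 4 array rows, so these groups were never compared within a row. The probes carry no gene names in the files, so each result is given by probe ID and probe sequence. All values below are normalized log2 ratios of a tank pool over the common reference.

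Most probes gave signal in every group. Of the 15208 probes, 91.2% ± 3.6 (SD, n = 4) were well above background in control arrays, 89.6% ± 0.93 (SD, n = 3) in KM4, 92.5% ± 2.0 (SD, n = 4) in TM5 and 92.2% ± 4.8 (SD, n = 4) in TM6. None of the effluents differed from control in this number by the exact permutation test (two-sided p = 0.543 for KM4, 0.600 for TM5 and 0.743 for TM6; adjusted over the 3 comparisons, 0.743 for each). The first principal component of the log ratios held 22.1% of the variance, and slide accounted for 64.7% of it and group for 2.8%. The 4 array rows, which include the difference between slides, accounted for 74.2%. Group accounted for 56.8% and the array rows for 18.4% of the second component, which held 15.7% of the variance.

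The comparison of KM4 with control asked which hypothalamic transcripts differed in fish held in that effluent. Of 14625 probes, 50 rose and 9 fell. This balance depended on the list, since 818 were higher and 699 lower at an unadjusted p under 0.05, and array weights called 503 higher and 597 lower. The first of these lists includes probes expected in both directions without any effect. With array weights the KM4 mean rested mostly on KM4_224 (weight 2.98, against 0.324 for each other KM4 array). Neither list therefore settles the direction. The median change was 0.82 on the log2 scale among probes that rose (1.76-fold) and -0.66 among those that fell (1.58-fold lower), and 14 of the 59 changed by more than 1 on the log2 scale. All 59 probes separated the KM4 from the control arrays without overlap, as did 8.9% of all tested probes, where chance gives 5.71%. In all, 1517 probes stood at an unadjusted p under 0.05, against 731.25 expected without any effect. Errors shared between probes can move this count, and KM4 and control shared 0 array rows, so the excess alone does not show an effect of the effluent.

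The largest rise was that of EA_Pp_51954a (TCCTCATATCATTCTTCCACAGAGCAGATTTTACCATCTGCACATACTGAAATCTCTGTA), at 0.86 ± 0.34 (SD, n = 3) in KM4 and -0.70 ± 0.34 (SD, n = 4) in control. The difference was 1.56 ± 0.19 (SE), a 2.95-fold rise with an adjusted p of 0.0045 in limma. EA_Pp_67409a (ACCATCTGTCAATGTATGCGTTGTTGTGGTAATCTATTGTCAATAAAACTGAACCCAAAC) rose from -0.59 ± 0.35 (SD, n = 4) to 0.97 ± 0.57 (SD, n = 3), a 2.93-fold change (limma adjusted p = 0.0175). EA_Pp_66039a (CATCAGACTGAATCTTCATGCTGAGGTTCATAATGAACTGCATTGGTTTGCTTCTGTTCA) fell by 1.21 ± 0.21 (SE) on the log2 scale, from 0.38 ± 0.26 (SD, n = 4) to -0.82 ± 0.40 (SD, n = 3), with a limma adjusted p of 0.0303. EA_Pp_59035a (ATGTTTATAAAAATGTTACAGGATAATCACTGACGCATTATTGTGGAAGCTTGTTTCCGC) fell by 1.19 ± 0.22 (SE), from 0.24 ± 0.47 (SD, n = 4) to -0.95 ± 0.15 (SD, n = 3), with a limma adjusted p of 0.0333. Both risers were also higher in KM4 than in TM5 and TM6 (limma adjusted p from 0.0081 to 0.0327), whereas the differences of both fallers from TM5 and TM6 did not pass (limma adjusted p from 0.0528 to 0.180). Against control, the 4 probes passed in 31, 26, 22 and 19 of 38 other settings, in the order given, of which Aquantile cannot change the result.

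The KM4 calls depended on the fit. No probe was called with array row as a fixed block, with median centring in place of loess, or from the 7 KM4 and control arrays alone, where 1116, 910 and 1377 probes stood at an unadjusted p under 0.05. The unmoderated test, the raw ratios of the series-wide table and slide 1 alone also gave 0 calls (1134, 60 and 1515 at an unadjusted p under 0.05), and slide 2 alone gave 1. Slide as a block gave 69 calls, of which 55 were among the 59, array row as a random block gave 20, all among the 59 (1420 at an unadjusted p under 0.05), and array weights gave 1100. Leaving out 1 array gave 8 to 60 calls. The count was 18 without KM4_111, 18 without KM4_221, 8 without KM4_224, 23 without CNHF_121, 14 without CNHF_211, 10 without CNHF_214, 36 without TM5_112, 29 without TM5_223, 28 without TM6_114, 29 without TM6_213 and 27 without TM6_222. The probes that rose had a median GC content of 35.0%, against 43.3% for all tested probes and 40% for the median of random lists matched on signal, and their median spot row was 52.5 of 192 (96.5 in the random lists).

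**Figure D1:**
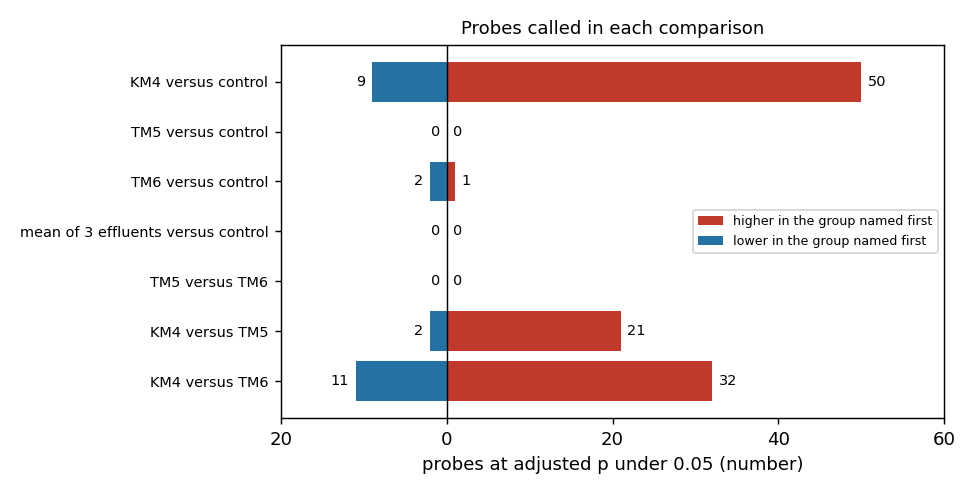
Number of probes at a limma adjusted p under 0.05 in each comparison (horizontal axis), drawn to the right where the group named first was higher and to the left where it was lower. KM4 differed from control at 59 probes, whereas TM5 and TM6 differed from control at 0 and 3.

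For TM5 against control, limma called 0 probes, and 464 stood at an unadjusted p under 0.05, fewer than the 731.25 expected without any effect. The smallest adjusted p was 0.157, for EA_Pp_55899a (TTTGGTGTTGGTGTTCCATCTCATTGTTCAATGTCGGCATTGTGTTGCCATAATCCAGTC), which lay at -0.41 ± 0.05 (SD, n = 4) in TM5 and 0.52 ± 0.21 (SD, n = 4) in control. It passed in 5 of 38 other settings (limma adjusted p from 0.0217 to 0.999), among them slide as a block (0.0289), array row as a random block (0.0314), the spatial correction (0.0217) and leaving out TM6_213 (0.0485). EA_Pp_56149a (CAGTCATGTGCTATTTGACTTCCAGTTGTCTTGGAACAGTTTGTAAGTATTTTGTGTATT) lay at -1.41 ± 0.26 (SD, n = 4) and -0.16 ± 0.39 (SD, n = 4), with a limma adjusted p of 0.222, and passed in 3 of 38 other settings (0.0272 to 0.998). EA_Pp_62311a (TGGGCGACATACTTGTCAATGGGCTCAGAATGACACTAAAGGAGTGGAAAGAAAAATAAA) lay at 0.56 ± 0.34 (SD, n = 4) in TM5 and -0.27 ± 0.11 (SD, n = 4) in control. EA_Pp_59941a (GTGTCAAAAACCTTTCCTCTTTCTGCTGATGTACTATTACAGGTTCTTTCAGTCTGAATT) lay at 0.45 ± 0.27 (SD, n = 4) and -0.22 ± 0.20 (SD, n = 4). Neither of these last differences passed. Of all tested probes, 2.0% separated the TM5 from the control arrays without overlap, where chance gives 2.86%.

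For TM6 against control, 3 probes changed. EA_Pp_56149a fell by 1.52 ± 0.21 (SE) on the log2 scale, to -1.68 ± 0.38 (SD, n = 4), with a limma adjusted p of 0.0185. EA_Pp_55899a fell by 1.15 ± 0.14 (SE), to -0.63 ± 0.34 (SD, n = 4), with a limma adjusted p of 0.0119. EA_Pp_53152a (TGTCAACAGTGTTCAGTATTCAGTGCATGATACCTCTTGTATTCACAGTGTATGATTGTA) rose by 0.81 ± 0.11 (SE), from -0.18 ± 0.10 (SD, n = 4) to 0.63 ± 0.18 (SD, n = 4), with a limma adjusted p of 0.0185. All 3 separated the TM6 from the control arrays without overlap, as did 3.4% of all tested probes, where chance gives 2.86%. EA_Pp_62311a was 1.02 ± 0.18 (SE) higher in TM6 and did not pass (limma adjusted p = 0.127). It passed in 8 of 38 other settings (limma adjusted p from 0.0030 to 0.996), among them slide as a block (0.0291), scaling between arrays (0.0117) and the TM6 and control arrays alone (0.0089). At an unadjusted p under 0.05 there were 460 probes, fewer than the 731.25 expected without any effect. The 3 calls depended on the fit. No probe was called with median centring, the unmoderated test, the raw ratios of the series-wide table or slide 1 alone (264, 775, 12 and 766 at an unadjusted p under 0.05), or without CNHF_121, CNHF_124, CNHF_214 or TM6_222. Scaling and the 8 TM6 and control arrays alone gave 1 call each, EA_Pp_62311a, and slide 2 alone gave 2, none of them among the 3. On those 8 arrays the 3 probes had limma adjusted p from 0.0876 to 0.170. The scanner software's processed signals and leaving out TM6_213 each left 1 of the 3. Over all 38 other settings, EA_Pp_56149a and EA_Pp_55899a passed in 26 each and EA_Pp_53152a in 21.

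**Figure D2:**
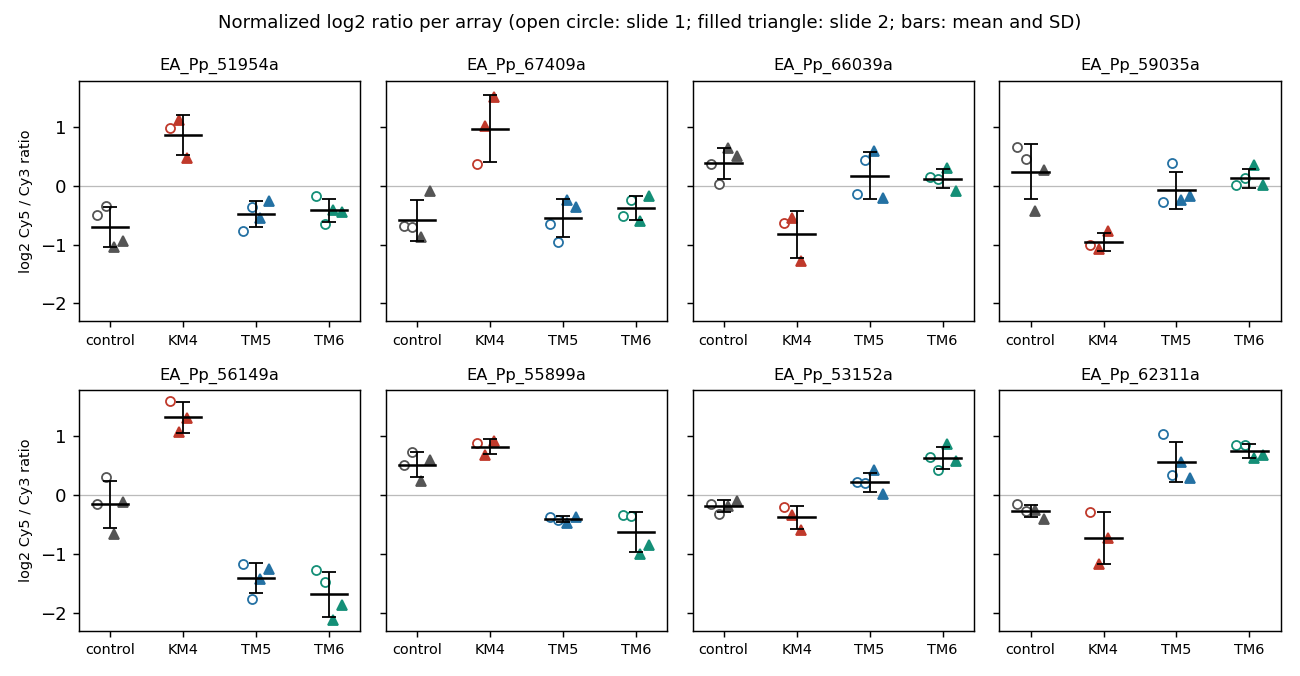
Normalized log2 Cy5 over Cy3 ratio (vertical axis) of 8 probes in each group (horizontal axis). Points are arrays, open circles on slide 1 and filled triangles on slide 2, and bars are the mean and SD. EA_Pp_56149a lay above all control arrays in the 3 KM4 arrays and below them in the 8 TM5 and TM6 arrays.

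The effluents were also compared with each other. KM4 differed from TM6 at 43 probes, with 32 higher and 11 lower in KM4, and from TM5 at 23 probes, with 21 higher and 2 lower. For TM6 the balance depended on the list, since 757 were higher and 835 lower at an unadjusted p under 0.05, and array weights called 792 higher and 1095 lower. For TM5 these were 689 and 421, and 335 and 298. Here too the KM4 mean with array weights rested mostly on KM4_224. Of the 50 probes that rose in KM4 against control, 20 were also higher in KM4 than in TM6 and 16 than in TM5, and 14 probes were called in all 3 comparisons. These comparisons share the KM4 arrays. EA_Pp_56149a showed the largest difference, 3.00 ± 0.23 (SE) on the log2 scale between KM4 and TM6 (8.02-fold, limma adjusted p = 1.97e-05) and 2.73 ± 0.23 (SE) between KM4 and TM5 (6.63-fold, limma adjusted p = 7.38e-05). EA_Pp_55899a was 2.75-fold higher and EA_Pp_62311a 2.80-fold lower in KM4 than in TM6. With slide as a block, KM4 differed from TM6 at 65 probes and from TM5 at 37, and the unmoderated test called 0 in both (1270 and 651 at an unadjusted p under 0.05). Median centring gave 9 and 12, array row as a fixed block 38 and 12, array row as a random block 86 and 28, and the arrays of the compared groups alone 11 and 6. Leaving out 1 array gave 13 to 85 for TM6, with 85 without KM4_111, 23 without KM4_221, 15 without KM4_224, 26 without TM6_113, 13 without TM6_114, 19 without TM6_213, 18 without TM6_222 and 26 without CNHF_121. For TM5 it gave 8 to 29, with 8 without KM4_221, 10 without KM4_224, 14 without TM5_112, 12 without TM5_122, and 15 without each of TM6_114, TM6_213, CNHF_121 and CNHF_214.

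For TM5 against TM6, limma called 0 probes, and the unmoderated test also called 0. At an unadjusted p under 0.05 there were 436, fewer than the 731.25 expected without any effect. The mean of the 3 effluents against control likewise gave 0 calls in limma, with 772 probes at an unadjusted p under 0.05 and 0 called by the unmoderated test. With slide as a block the mean gave 2 calls, both higher, with 1062 probes at an unadjusted p under 0.05. A test for any difference among the 4 groups called 24 probes, and the unmoderated test 4. The count was 36 with slide as a block, 10 with array row as a fixed block, 34 with array row as a random block, 8 with median centring and 6 with the scanner software's processed signals. Leaving out 1 array gave 9 to 29, with 15 without TM6_114, 13 without KM4_221 and 9 without KM4_224.

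**Figure D3:**
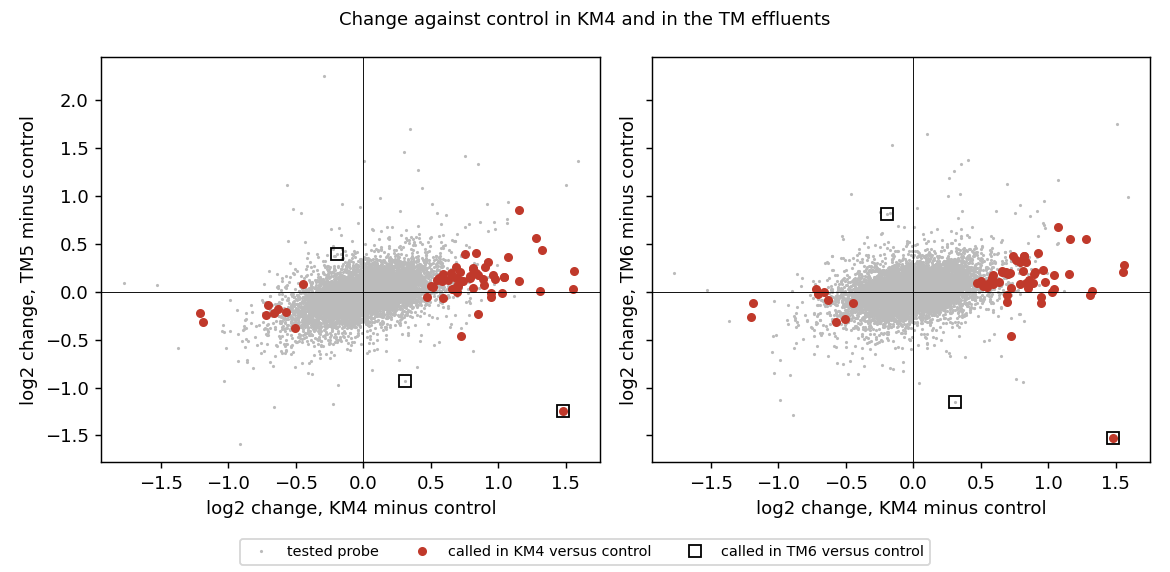
Log2 change against control in KM4 (horizontal axis) and in TM5 or TM6 (vertical axis), where each point is a probe, red points were called in KM4 and squares in TM6. EA_Pp_56149a lies at 1.48 in KM4, -1.25 in TM5 and -1.52 in TM6.

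Across probes, the changes against control correlated at 0.47 between KM4 and TM5, 0.33 between KM4 and TM6 and 0.55 between TM5 and TM6 (jackknife SE over arrays 0.22, 0.25 and 0.23). Probes are not independent replicates, and the 3 comparisons share their controls. Simulated unchanged groups against shared controls gave 0.46, 0.46 and 0.50, with errors drawn independently for each probe. Real arrays share errors between probes, and 100 reassignments of whole arrays, after group means were removed, gave 95% ranges of 0.012 to 0.788, 0.190 to 0.781 and 0.144 to 0.796, which hold the observed values. The reassignments ignored slide and array row, which can widen these ranges. The covariances were 0.0159, 0.0104 and 0.0124 against simulated values of 0.0128, 0.0128 and 0.0129. With the controls split so that no control array was shared, the mean correlation over 3 splits was 0.12, -0.0054 and 0.050. At an unadjusted p under 0.05, KM4 and TM5 shared 69 higher and 74 lower probes, KM4 and TM6 86 and 31, and TM5 and TM6 59 and 50. The simulation with independent errors gave 71.6 and 72.7, 72.0 and 75.0, and 80.5 and 79.0, whereas independent lists would share 12.4 and 11.6, 15.4 and 8.84, and 4.16 and 3.07.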

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

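The patterns weighed here were noticed in the data first. The size limits that decide each test were set before its value was seen, except for the place on the array of the probes that rose. The counts of changes that shrank with array row as a fixed block, and the random block, were chosen after the result was seen.

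EA_Pp_56149a stood out because it lay on opposite sides of control in KM4 and in the TM effluents. It passed against control in KM4 and TM6 but not in TM5. KM4 exceeded TM5 by 2.73 and TM6 by 3.00 on the log2 scale, and both differences passed when tested directly (limma adjusted p = 7.38e-05 and 1.97e-05). All 3 KM4 arrays lay above the 4 control arrays and all 8 TM arrays lay below them, which is the pattern that flagged the probe and no further evidence. Its call in KM4 against control was lost, like all others there, with array row as a fixed block, with median centring and from the KM4 and control arrays alone. Its GC content was 35% and its spot row 12, low like the medians of the probes that rose in KM4. The KM4 group, with 3 arrays, was not checked for an outlying array. In the control, TM5 and TM6 groups, 0 of 30 sets of 4 values stood out, over all named probes and the number of probes well above background. The value of 1.5 by chance holds for values that were not picked, whereas named probes were picked by their changes. This check therefore decides nothing about EA_Pp_56149a.

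The probes that rose in KM4 were poor in G and C. Their median GC content of 35.0% lay at percentile 0.01 of 10000 random lists of 50 probes matched on mean signal, whose median was 40%. Across probes, the KM4 change correlated with GC content at -0.23, and the steepest array trends were those of CNHF_211 (0.30) and KM4_224 (-0.23). Subtracting each array's GC trend left the median change of these probes at 0.74, against 0.82 before, with 36 of 50 still called. This argues against such a trend only as the whole cause of the size of their changes. The probes were picked for large uncorrected changes, so it does not decide why the called list was poor in G and C. Without both arrays the median was 0.71 but 5 of 50 were called, with a smaller change, a median SE of 0.153 against 0.143 before, and 2 arrays fewer. An effect of the effluent and a contribution of probe composition stay open.

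The same probes lay together on the array, with a median spot row of 52.5 at percentile 0.01 of the random lists. The spread of spot rows of the 9 probes that fell was not unusual (percentile 10.9), although they had first seemed clustered. The 4 arrays in the first row of slide 1, which hold KM4_111 but no control, had the strongest smooth surfaces (SD 0.144 to 0.218, against 0.018 to 0.092 elsewhere). Subtracting the surfaces left the median rise at 0.78 and the median fall, as a size, at 0.62 against 0.66 before, with 42 of 50 and 7 of 9 still called. This argues against a smooth spatial trend only as the whole cause of the size of these changes. The surfaces were small beside changes picked for their size, so it does not decide why the probes that rose lay together. A spatial contribution stays open, and sharper local effects were not tested.

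With array row as a fixed block, 0 of the 59 KM4 calls passed, whereas with array row as a random block 20 of the 59 passed, among them EA_Pp_51954a (limma adjusted p = 0.0086) and EA_Pp_67409a (0.0433) but neither EA_Pp_66039a (0.0961) nor EA_Pp_59035a (0.0721). Over all other settings the adjusted p of these 4 ran from 0.00037 to 0.9997. With the fixed block the median change in the called direction was 0.76, against 0.79 before, while the median SE grew from 0.139 to 0.191. Of the 59 changes, 39 became smaller, 4 of them by over 1.5 times. EA_Pp_66039a went from -1.21 to -0.71, EA_Pp_59035a from -1.19 to -0.78 and EA_Pp_67409a from 1.55 to 1.20, whereas EA_Pp_51954a went from 1.56 to 1.68. The calls thus ended mainly with the larger error, and for some probes also with a smaller change. The median, 0.79 for the probes that rose and 0.69 as a size for those that fell, argues against an additive shift of array rows as the whole cause for the list. KM4 and control shared 0 of the 4 array rows, however, so this estimate runs through the TM5 and TM6 arrays, and a part played by array position stays open, above all for the probes that shrank. An effect of the effluent remains open, and no biological explanation was tested.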

How the results depend on the processing

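Alternatives chosen after seeing the data were the authors' normalized channels, the GC and spatial corrections, array row as a block, leaving out KM4_224 and CNHF_211 together, and leaving out arrays for detection and for the correlations. Counts are called probes, in the order KM4, TM5 and TM6 against control, any difference, mean of effluents, TM5 against TM6, KM4 against TM5 and KM4 against TM6 (59, 0, 3, 24, 0, 0, 23 and 43 as reported), and only counts that moved by over 1.5 times are given. The cause was not tested unless stated. With normexp at offset 0 they were 32 for KM4, 13 for KM4 against TM5 and 27 for KM4 against TM6. The scanner software's processed signals gave 11 for KM4, 1 for TM6, 6 for any difference, 6 for KM4 against TM5 and 12 for KM4 against TM6. Median centring gave 0 for KM4, 0 for TM6, 8 for any difference, 12 for KM4 against TM5 and 9 for KM4 against TM6. Scaling between arrays gave 8 for KM4 (8 higher and 0 lower), 1 for TM6, 10 for any difference, 1 for the mean, 9 for KM4 against TM5 and 10 for KM4 against TM6. The raw ratios of the series-wide table gave 0 for KM4, TM6, any difference, KM4 against TM5 and KM4 against TM6. Slide as a block gave 1 for TM5, 2 for the mean, 37 for KM4 against TM5 and 65 for KM4 against TM6. Slide 1 alone, with 1 KM4 array assumed to vary like the other groups, gave 1 for the mean and 0 for KM4, TM6, any difference, KM4 against TM5 and KM4 against TM6. Slide 2 alone gave 1 for KM4, 1 for TM5, 3 for any difference, 2 for the mean, 1 for TM5 against TM6, 3 for KM4 against TM5 and 3 for KM4 against TM6. Both use fewer arrays. Array weights gave 1100 for KM4 (503 higher and 597 lower), 2 for TM5, 10 for TM6, 967 for any difference, 2 for the mean, 633 for KM4 against TM5 and 1887 for KM4 against TM6. There KM4_224 had a weight of 2.98 and the other KM4 arrays 0.324 each, so the KM4 mean rested mostly on 1 array. The arrays of the compared groups alone gave 0 for KM4, 1 for TM6, 6 for KM4 against TM5 and 11 for KM4 against TM6. The unmoderated test gave 0 for KM4, TM6, KM4 against TM5 and KM4 against TM6, and 4 for any difference. At an adjusted p under 0.10 there were 94 for KM4, 40 for any difference, 38 for KM4 against TM5 and 105 for KM4 against TM6. At an unadjusted p under 0.05 there were 1517, 464, 460, 1020, 772, 436, 1110 and 1592. Subtracting the spatial surface gave 109 for KM4, of which 49 were among the 59, with 3 for TM5, 8 for TM6, 48 for any difference and 116 for KM4 against TM6. Array row as a fixed block gave 0 for KM4, 10 for any difference and 12 for KM4 against TM5, and as a random block 20 for KM4, 2 for TM5 and 86 for KM4 against TM6. Without KM4_224 and CNHF_211 there were 7 for KM4, 11 for any difference, 12 for KM4 against TM5 and 18 for KM4 against TM6. Aquantile leaves log ratios as they are and tests nothing. No paired analysis was possible because the groups share no replicate codes. The gene list alternatives were not run, since no probe could be matched to a gene.

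Leaving out each array in turn gave 8 to 60 calls for KM4, 0 to 1 for TM5, 0 to 4 for TM6, 9 to 29 for any difference, 0 for the mean and for TM5 against TM6, 8 to 29 for KM4 against TM5 and 13 to 85 for KM4 against TM6. For KM4 the count was 18 without KM4_111, 18 without KM4_221, 8 without KM4_224, 23 without CNHF_121, 14 without CNHF_211, 10 without CNHF_214, 36 without TM5_112, 29 without TM5_223, 28 without TM6_114, 29 without TM6_213 and 27 without TM6_222. For TM6 it was 0 without CNHF_121, CNHF_124, CNHF_214 or TM6_222, and 1 without TM6_213, and TM5 had 1 without TM6_213. Any difference had 15 without TM6_114, 13 without KM4_221 and 9 without KM4_224. KM4 against TM5 had 14 without TM5_112, 12 without TM5_122, 8 without KM4_221, 10 without KM4_224, and 15 without each of TM6_114, TM6_213, CNHF_121 and CNHF_214. KM4 against TM6 had 85 without KM4_111, 23 without KM4_221, 15 without KM4_224, 26 without TM6_113, 13 without TM6_114, 19 without TM6_213, 18 without TM6_222 and 26 without CNHF_121. The difference in probes well above background ran from -477.3 to -52.3 for KM4, from -33.5 to 391.5 for TM5 and from -84.2 to 444.5 for TM6. It changed sign for TM5 without CNHF_211 (-33.5) and for TM6 without CNHF_211 (-84.0) or TM6_114 (-84.2). The correlations ran from 0.35 to 0.60 for KM4 and TM5, 0.20 to 0.49 for KM4 and TM6 and 0.42 to 0.68 for TM5 and TM6. With split controls they were 0.12, -0.0054 and 0.050, since no control array was then shared. Over the values of named probes under other settings, 0 changed direction (partly fixed in advance, since Aquantile, other filters, other variance models and leaving out arrays of other groups do not move most of these differences), 345 kept their side of the threshold, 95 no longer passed and 16 newly passed.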

Other observations

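The comparison of TM5 and TM6 together against control and the splits within slides were chosen after the first values were seen, and the split counts of the other comparisons were planned. Taken as 1 group of 8 arrays, TM5 and TM6 differed from control at 2 probes, EA_Pp_55899a (-1.04 ± 0.13 SE on the log2 scale, limma adjusted p = 0.0077) and EA_Pp_56149a (-1.39 ± 0.19 SE, limma adjusted p = 0.0108), both below all control arrays in 8 of 8 arrays. Of 100 splits of the 12 arrays into 8 and 4, 1 gave as many calls, the real one, and the highest of the others gave 1. Among 100 splits that kept the numbers on each slide, 2 gave as many, and the highest of the others gave 10. The count was 4 with slide as a block, 3 with array row as a fixed block, 4 with the spatial surface subtracted, and 0 with the scanner software's processed signals. At an unadjusted p under 0.05 there were 500 probes, 658 with slide as a block and 732 with array row as a fixed block, where about 731 are expected without effect. These counts give no sign of a broad response shared by the TM effluents and do not exclude one.

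The probes that rose in KM4 had a median change of 0.14 in TM5 (from -1.25 to 0.85) and 0.16 in TM6 (from -1.52 to 0.68), in comparisons that share the control arrays, so a value above 0 also arises without any effect.

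Other splits of the same arrays were counted for each comparison. For KM4 against control, 1 of 35 splits gave as many calls as the real 59, which was the real split itself. The highest of the others gave 1. This is the smallest share that 35 splits allow, and it lies under 0.05 only for splits that ignore slide and array row. The shares were not adjusted over the comparisons, so chance is not excluded. Because KM4 and control shared 0 array rows, the real split also parts the array rows, so the count says nothing against array position. The limma count was 0 with array row as a fixed block (1116 at an unadjusted p under 0.05) and 20 with array row as a random block. The real split was also the only one with as many calls for TM6 against control (real 3, highest other 0, 1 of 35 splits) and KM4 against TM6 (real 43, highest other 1, 1 of 35 splits). The same held for any difference among the groups (real 24, highest other 7, 1 of 100 splits). TM6 shared 1 of the 4 array rows with control and 2 with KM4, so these real splits also part some array rows. Only 18 splits of each pair of groups keep the numbers on each slide, too few for a share under 0.05, and the highest of the others among them gave 0 for KM4 against control, TM6 against control and KM4 against TM6. For any difference, 1 of 100 splits within slides gave as many, and the highest of the others gave 4. For KM4 against TM5, 2 of 35 splits gave at least the real 23, so chance was not excluded. The other gave 51 and set TM5_212, KM4_221 and KM4_224, all on slide 2, against 3 slide 1 arrays and TM5_223. That split follows the slide except for TM5_223, and it keeps 2 of the 3 KM4 arrays together, so slide and effluent cannot be told apart in it. The real comparison gave 37 calls with slide as a block, while the highest of the other splits within slides gave 1. Where the real count was 0, every split gives as many, so the splits decide nothing for TM5 against control (highest other 2, 35 of 35 splits), TM5 against TM6 (highest other 2, 35 of 35 splits) and the mean of the effluents (highest other 59, 100 of 100 splits). The split that gave 59 set KM4_221, KM4_224, TM5_212 and CNHF_124 against the rest. It holds 2 of the 3 KM4 arrays and 3 arrays of slide 2, so a structure of the arrays and a KM4 difference cannot be told apart in it.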
